A study of Mus musculus with 4 samples.

How the data were processed

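RNA from 4 mouse spleen samples was sequenced, 2 labelled wild-type and 2 labelled KLHL3-KI, and the groups and replicate numbers were taken from the sample titles. The labels do not say that the samples are separate animals, so no p can be taken to measure the spread between animals. The limma p values join the spread between these samples with variances pooled across all genes. Permutation p values, and camera p values at the preset correlation, measure spread over genes. The knock-in allele, the age and the sex of the mice are not given in the sources used here. The library numbers in the descriptions differ from the replicate numbers in the titles for all libraries but KLHL3-KI replicate 1, and each column was matched to its sample by the library name.

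Per the submitters' processing notes, reads were processed with Trimmomatic 0.38, Bowtie2, RSEM 1.3.0 and edgeR with genome build GRCm39, and the roles and order of the tools, the annotation and any filter are not stated. The deposited table, called normalized counts by the authors, holds a normalized signal per gene and library for 23763 genes. It was checked that every value is a whole multiple of the smallest value of its library (100% of values, within 0.001 of a whole read), so the whole reads were recovered by dividing by that value. The values are therefore read counts divided by 1 factor per library, on a scale of an effective library size. The 4 ratios of effective to summed size (1.05, 1.07, 0.947 and 0.939) multiply to 1, which is how edgeR scaling factors are built. This naming comes from the values and not from the notes. The recovered reads were 8535483 and 8975415 in WT and 9586677 and 10933023 in KLHL3-KI replicates 1 and 2, and 1 read was worth 0.112, 0.104, 0.110 and 0.0974 in the table. Precision is limited by these depths and by n = 2 per group. The spread between replicates was over counting noise, with a chi-square per degree of freedom of 4.75 between the WT and 8.52 between the KLHL3-KI libraries, against 30.9 to 53.2 between libraries of different groups. The Pearson correlation of log2 values across genes was 0.989 within each group and 0.949 to 0.967 between groups, where genes are not independent replicates.

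Gene names came from an annotation of build GRCm38, since the table gives only Ensembl identifiers; 23605 of them (99.3%) had a name, 158 had none and 21 names were shared by more than 1 identifier. No coordinates are given because the builds differ. Histone genes keep the older names of that annotation. The most abundant gene, with 1.69% to 2.25% of the reads of a library, had no name and is not described.

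Genes with a mean value of at least 1 over the 4 libraries were tested, 16970 in number, and 6793 were under that minimum. Values were put on the scale log2(value + 1), with a pseudocount of 1, and compared with limma 3.58.1 in R 4.3.3 (a linear model with a mean-variance trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). Each of 32 gene lists was written from general knowledge of the spleen, of red cells and of the WNK-KLHL3 pathway, and the 30 lists with at least 5 tested members were compared with all other genes by limma camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Lists share members: for example, 8 WNK-KLHL3 genes stand in another list. The groups, lists, tests, thresholds, the rule for named genes and all alternatives but those named below as added were fixed before the data were examined. A first look at the lists used camera without a variance trend and gave the same number of lists, 19; the values reported use the trend, as the gene test does. The rule named Klhl3 and the other WNK-KLHL3 genes first. It then named in each direction the 8 genes with the largest log2 fold change among those with an adjusted p under 0.05 and with both KLHL3-KI values beyond both WT values. Predicted and clone gene models, immunoglobulin and T cell receptor segments, pseudogenes and ribosomal RNA were passed over there (0 among rises, 16 among falls). Last, it named up to 4 members with the lowest p of each list. It named 151 genes, and other genes were named after their values were seen, among them Hbb-bs and the genes of the lists added later. Some genes that the rule named or that passed are not reported here.

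An exact test on 2 against 2 libraries cannot go below p = 0.333, so single genes were tested only in models across all genes. The recovered reads of the same genes were also compared with edgeR 4.0.16 (quasi-likelihood, TMM scaling) and DESeq2 1.42.0. Other alternatives for the values were pseudocounts of 0.1 and 5, no filter and a mean of at least 5, quantile normalization, median-ratio rescaling, and removal of haemoglobin, immunoglobulin and mitochondrial genes before rescaling. Alternatives for the tests were no variance trend, a robust variance model, an adjusted p of 0.1, a replicate block and an estimated inter-gene correlation. With the estimate, camera takes its degrees of freedom from the 4 libraries and not from the genes, so a pass was hard to reach. Each library was also left out in turn, where the lone sample of a group is assumed to vary like the other group. Scaling the recovered reads to equal totals, and camera without a variance trend, were added after seeing the data. The labels do not say whether the replicate numbers pair the samples. The deviations of replicate 1 from its group mean had a correlation of -0.03 (Spearman -0.04) between the groups across 16970 genes. No shared deviation was thus seen, which does not settle whether the samples were paired.

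The gene test was tested on simulated data with the depths of these libraries, 17025 genes, a dispersion of 0.01 and 200 genes changed. There limma called 100% of the genes changed 4-fold, 70% of those changed 2-fold, 32% of those changed 1.5-fold, 95.9% of those at 0.25-fold and 0.0238% of the unchanged genes. The simulated genes varied independently and without a shift in scaling. These rates therefore do not carry over to the data, where 3866 genes passed.

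A further 11 lists were written after the data were seen: eosinophil granule, white pulp, naive T cell, regulatory and effector T cell, erythroid feedback and stress erythropoiesis, cholesterol synthesis, cytosolic ribosomal protein, primary granule, mature neutrophil, adult globin and RNA without a poly(A) tail, the last from names present in the table. The medians of list members were compared by permutation tests over genes with scipy 1.17.1, two-sided, exact for lists under 10 genes and with 100000 resamples otherwise. S100a8 and S100a9 were added to the mature neutrophil genes in a further contrast after the first was seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures. Isoforms, splicing, variants and the knock-in allele itself were not analysed here, since the table holds 1 value per gene.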

Results

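The data were gene expression values from spleen RNA of C57BL/6J mice at baseline, measured by directional RNA sequencing after depletion of ribosomal RNA. The 4 libraries formed 2 groups, wild-type (WT) and KLHL3 knock-in (KLHL3-KI), with 2 libraries in each. The deposited table held 23763 genes as a scaled read count, and the whole reads behind it came to 8535483 and 8975415 in WT replicates 1 and 2 and to 9586677 and 10933023 in KLHL3-KI replicates 1 and 2. All values below are scaled read counts, given as mean ± SD with n = 2 libraries per group, and log2 fold changes are KLHL3-KI minus WT with their standard error (SE). All 4 libraries expressed the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, and Xist did not exceed 1.07 in any of them.

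The comparison asked how the spleen transcriptome of KLHL3-KI mice differed from that of wild-type mice. Red cell precursor, cell division, histone and neutrophil granule genes were higher in both KLHL3-KI libraries, while T cell and B cell genes were lower. The erythroid transcription factor Klf1 rose from 18.7 ± 2.44 to 172 ± 26.1, the proliferation marker Mki67 from 421 ± 40.5 to 2402 ± 333, and the neutrophil granule gene Ngp from 16.6 ± 11.5 to 319 ± 74.3. The T cell receptor component Cd3e fell from 56.9 ± 4.31 to 30.7 ± 1.28, and the low-affinity IgE receptor Fcer2a of B cells from 140 ± 0.567 to 75.53 ± 9.996. Of 16970 genes tested with limma, 3866 passed a Benjamini-Hochberg adjusted p of 0.05, of which 2583 rose and 1283 fell. The log2 fold change was over 1 for 1017 of the genes that rose and under -1 for 52 of the genes that fell. The values of the groups did not overlap for 64.7% of the tested genes, where the average over all splits of the 4 libraries into pairs is 33.3%. Genes share the same 4 libraries, so the gap between these shares does not measure an excess over chance. Of 30 gene lists tested with limma camera at a preset correlation, 13 went up and 6 went down. None of the 30 passed with a correlation estimated from these libraries, where the lowest adjusted p was 0.441 and the lowest unadjusted p 0.0818. That setting takes its degrees of freedom from the 4 libraries, so a pass was hard to reach. The NK cell list lost its call at an estimated correlation of -0.00938, so such losses do not measure correlation alone.
The split between rises and falls depended on the scaling. With median-ratio rescaling 2632 rose and 1270 fell, close to the counts above. After quantile normalization 2041 rose and 2369 fell. With haemoglobin, immunoglobulin and mitochondrial genes removed and the remaining totals made equal, 2087 rose and 2971 fell. Equal total reads per library, with no gene removed, gave 1912 and 3126. The median log2 fold change of all genes was -0.10, -0.14 and -0.16 there. The count that passed was 2224 without WT replicate 1 and 1653 without WT replicate 2, and the count that fell was 803 without KLHL3-KI replicate 2.

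**Figure D1:**
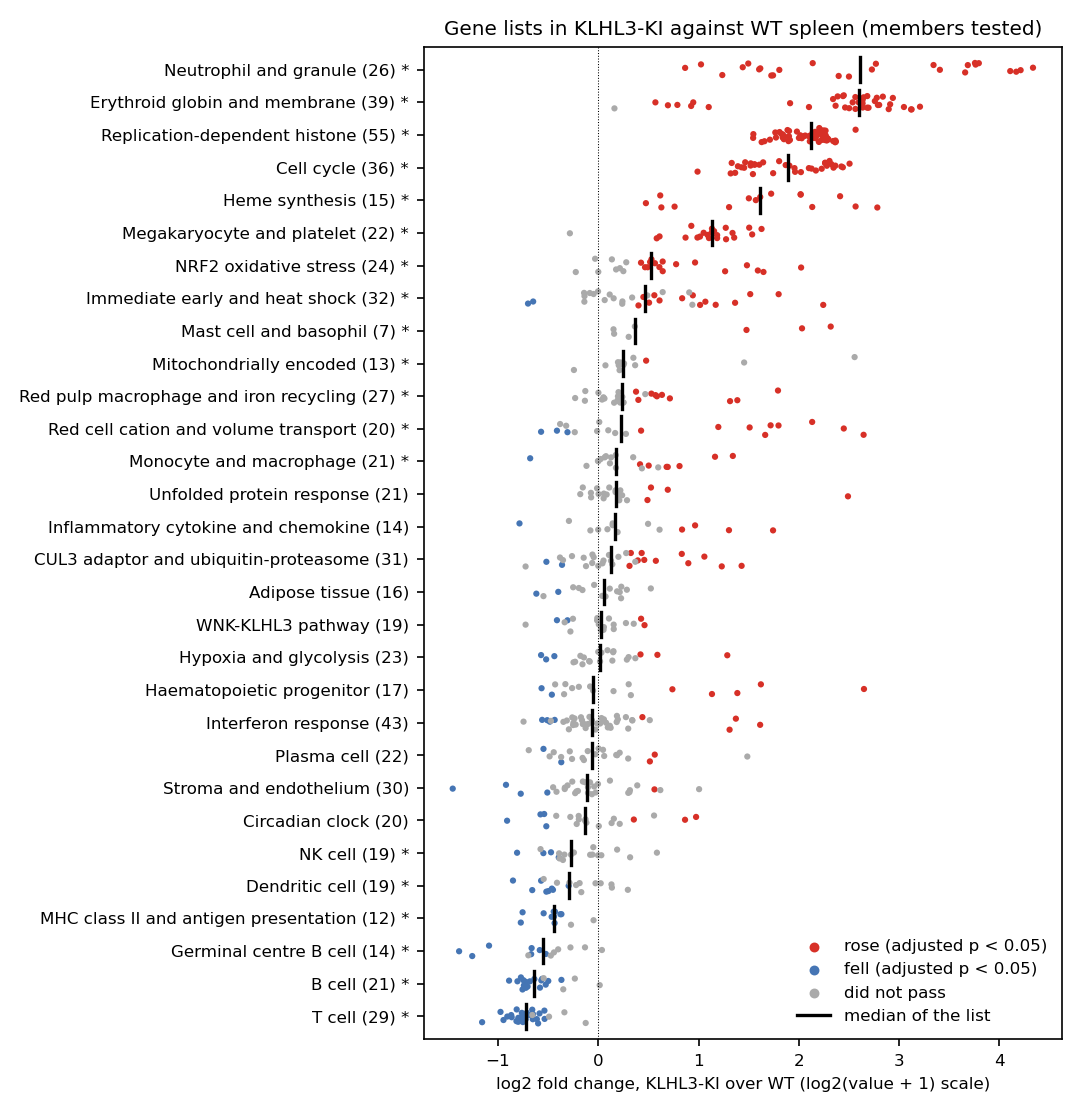
Log2 fold change, KLHL3-KI over WT, of each tested member (points) of the 30 gene lists, coloured by whether the gene rose, fell or did not pass the limma test, with the list median as a bar; an asterisk marks an adjusted camera p under 0.05 at the preset correlation, and the number of tested members is in parentheses. The list medians run from -0.72 for the T cell list to 2.61 for the neutrophil and granule list.

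Klhl3 (ENSMUSG00000014164), which encodes the substrate adaptor of a CUL3 ubiquitin ligase that targets WNK kinases, was measured at 3.85 ± 1.17 in WT and 1.95 ± 0.827 in KLHL3-KI spleen, a log2 fold change of -0.72 (SE 0.27). It did not pass the limma test (adjusted p = 0.0895) and rested on 27 and 45 reads in the WT libraries and 23 and 14 in the KLHL3-KI libraries. Its log2 fold change ran from -1.01 to -0.43 without 1 library, and was -1.01 with edgeR and -0.996 with DESeq2. Wnk1 (ENSMUSG00000045962), the kinase upstream of cation-chloride cotransport, rose from 591 ± 2.72 to 815 ± 37.0, a log2 fold change of 0.46 (SE 0.09, limma adjusted p = 0.00653). Among the potassium-chloride cotransporters, Slc12a4 rose by 0.43 on the log2 scale (SE 0.13), while Slc12a7 fell by 0.41 (SE 0.10), with limma adjusted p values of 0.0438 and 0.0133. Piezo1 (ENSMUSG00000014444), a mechanically gated cation channel, was at 83.4 ± 10.4 in WT and 101.2 ± 13.3 in KLHL3-KI spleen and did not pass (log2 fold change 0.28, SE 0.12, limma adjusted p = 0.145). Its log2 fold change ran from 0.14 to 0.41 without 1 library. Further members of the WNK-KLHL3 list did not pass. These were Klhl2, Cul3, Rbx1, Nedd8, Wnk3, Wnk4, Stk39, Oxsr1, Cab39, Cab39l, Slc12a1, Slc12a2 and Slc12a3, with log2 fold changes between -0.34 and 0.35. Of 19 tested members 2 rose and 2 fell (2 and 2 adjusted over the list alone). The list itself did not pass (camera adjusted p = 0.955), with a median of 0.03, a mean of -0.01 and test direction down. Wnk2 was under the minimum level, with values from 0 to 0.727.
The limma adjusted p of Klhl3 ranged from 0.0130 to 0.437 over the alternatives. It passed without KLHL3-KI replicate 1 (0.0130), with haemoglobin, immunoglobulin and mitochondrial genes removed (0.0399) and with equal total reads (0.0489). That of Piezo1 ranged from 0.0260, without KLHL3-KI replicate 1, to 0.544. Without WT replicate 2 the calls were lost for Wnk1 (limma adjusted p = 0.0604, range over all alternatives from 3.88e-05 with DESeq2 to 0.0618 with limma), Slc12a4 (0.110, range 0.0291 to 0.211) and Slc12a7 (0.104, range 0.00133 to 0.104). Those of Slc12a4 and Slc12a7 were also lost without WT replicate 1 (0.211 and 0.0780). That of Slc12a4 was also lost without KLHL3-KI replicate 2 (0.195), after quantile normalization (0.118), with haemoglobin, immunoglobulin and mitochondrial genes removed (0.117), with equal total reads (0.159), with no filter (0.0594), with edgeR (0.0525) and with DESeq2 (0.184). That of Wnk1 was lost after quantile normalization (0.0618), and without a variance trend those of Wnk1, Slc12a4 and Slc12a7 were lost (0.0556, 0.0872 and 0.0703). In this list 0 rose and 2 fell after quantile normalization, and 1 rose and 3 fell with haemoglobin, immunoglobulin and mitochondrial genes removed or with equal total reads. There were 0 rises and 0 falls without WT replicate 2 or without a variance trend, 1 and 0 without WT replicate 1, and 1 and 1 without KLHL3-KI replicate 2 or with no filter.

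Genes of red cell precursors rose together. Of 39 tested members of the erythroid globin and membrane list, 38 rose and none fell, both over all genes and adjusted over the list alone, with a median log2 fold change of 2.60. Klf1, the transcription factor of erythroid maturation, rose by 3.12 (SE 0.13), Rhd, a Rhesus blood group membrane protein, by 2.91 (SE 0.13), and Car1, an erythroid carbonic anhydrase, by 2.70 (SE 0.11), each with a limma adjusted p of 2.17e-06. The adult globin genes were the most abundant members and rose less. Hbb-bs went from 9102 ± 832 to 15698 ± 410, a log2 fold change of 0.79 (SE 0.15), and values of single globin genes are uncertain because near-identical copies share reads. All 15 heme synthesis genes rose (15 adjusted over the list alone, median 1.62), among them the mitochondrial transporter Abcb10 at 2.41 (SE 0.11) and Cpox at 2.57 (SE 0.15). Of 20 red cell cation and volume transport genes, 9 rose and 3 fell (9 and 3 adjusted over the list alone, median 0.22). The anion exchanger Slc4a1 rose by 2.45 (SE 0.13), the water channel Aqp1 by 2.65 (SE 0.14) and the urea transporter Slc14a1 by 2.13 (SE 0.11). Slc12a7 and the glucose transporter Slc2a1 were among those that fell. Of 27 red pulp macrophage and iron recycling genes, 10 rose and none fell (11 and none adjusted over the list alone, median 0.24). Among these were Blvrb at 1.79 (SE 0.10), which reduces biliverdin, Paqr9 at 1.39 (SE 0.10) and the iron transporter Slc11a2 at 1.31 (SE 0.11), of which Blvrb and Slc11a2 are also known from red cell precursors. Spic, the transcription factor of red pulp macrophages, was at 97.0 in WT and 113 in KLHL3-KI spleen and did not pass (chosen after its values were seen).
The 4 lists passed limma camera at the preset correlation with adjusted p values of 7.13e-37 (erythroid), 1.05e-15 (heme synthesis), 0.00855 (red cell transport) and 1.16e-04 (red pulp). The calls were lost at adjusted p = 0.441 with an estimated correlation for the erythroid and heme synthesis lists, adjusted p = 0.468 with an estimated correlation for red cell transport and adjusted p = 0.442 with an estimated correlation for red pulp. Without WT replicate 1, 0 of the red cell transport genes fell, and without WT replicate 2, 1 of them fell and 6 red pulp genes rose. With no variance trend 0 red cell transport genes fell and 6 red pulp genes rose, and 5 red cell transport genes fell with haemoglobin, immunoglobulin and mitochondrial genes removed and with equal total reads. Slc2a1 lost its call without WT replicate 1 (0.1004) and without a variance trend (0.0530).

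Cell division genes rose throughout the list fixed for them. All 36 cell cycle genes rose (36 adjusted over the list alone), with log2 fold changes from 0.99 to 2.51 and a median of 1.89. Mki67 rose by 2.51 (SE 0.12), the S and G2 phase cyclin Ccna2 by 2.44 (SE 0.11), the kinetochore protein Cenpf by 2.33 (SE 0.11) and the mitotic kinase Cdk1 by 2.28 (SE 0.12), each with a limma adjusted p of 2.17e-06. All 55 tested replication-dependent histone genes rose as well (55 adjusted over the list alone), from 1.54 to 2.57 with a median of 2.13. Hist1h4a went from 109 ± 3.74 to 560 ± 51.5 and Hist1h3b from 216 ± 14.6 to 1058 ± 68.0. Values of single histone genes are uncertain where near-identical copies share reads. Histone genes took 0.634% ± 0.0307 of all reads in WT and 2.32% ± 0.194 in KLHL3-KI libraries, and cell cycle genes took 0.204% ± 0.0138 and 0.738% ± 0.0948. Both lists passed limma camera at the preset correlation (adjusted p = 1.01e-34 and 4.24e-54) and lost the call at adjusted p = 0.441 with an estimated correlation.

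**Figure D2:**
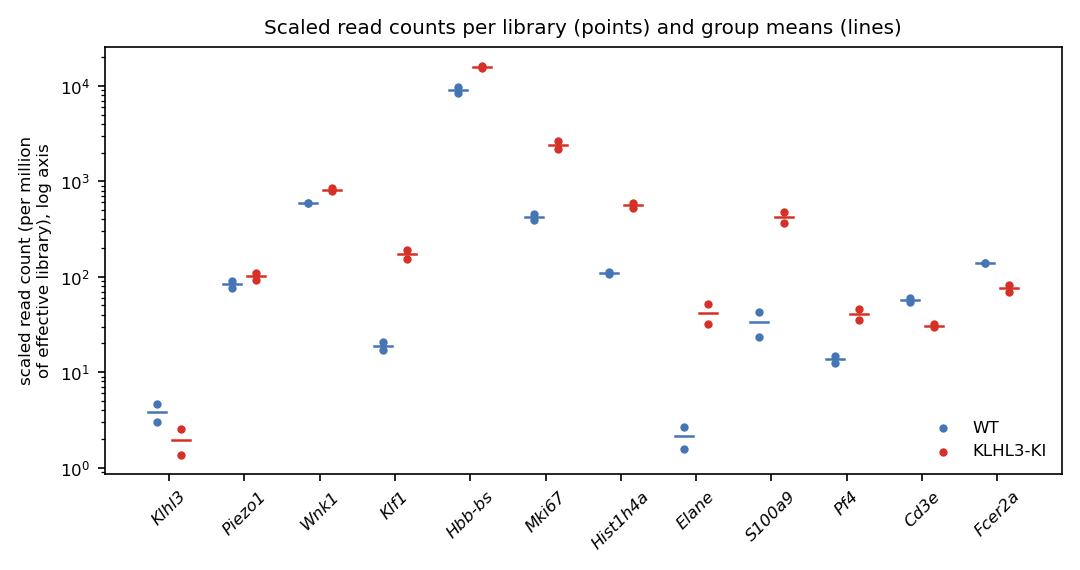
Scaled read count (log axis) of 12 genes in each library (points) with the group mean (line), WT against KLHL3-KI. Klf1, Mki67, Hist1h4a, Elane, S100a9 and Pf4 were higher in both KLHL3-KI libraries than in both WT libraries, and Cd3e and Fcer2a were lower; Klhl3 and Piezo1 did not pass the test.

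Genes of the neutrophil and granule list made up the 8 largest rises among called genes on the log2(value + 1) scale. Ngp rose by 4.33 on the log2 scale (SE 0.36), lactoferrin (Ltf) by 4.21 (SE 0.40), the cathelicidin Camp by 4.17 (SE 0.44) and lipocalin 2 (Lcn2) by 4.11 (SE 0.27), followed by Chil3 at 3.79, S100a8 at 3.76, neutrophil elastase (Elane) at 3.76 and S100a9 at 3.68. All 26 tested genes of the neutrophil and granule list rose (26 adjusted over the list alone, median 2.61). The collagenase Mmp8 went from 2.00 ± 0.182 to 31.0 ± 5.86. Of 22 megakaryocyte and platelet genes, 21 rose (21 adjusted over the list alone, median 1.13), including the platelet chemokines Ppbp at 1.53 (SE 0.12) and Pf4 at 1.51 (SE 0.16). Of 21 monocyte and macrophage genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.18). The integrin Itgam rose by 1.16 (SE 0.16) and the chemokine receptor Ccr2 by 0.81 (SE 0.12), while Cx3cr1, named after its values were seen, fell by 0.68 (SE 0.17). Of 7 mast cell and basophil genes, Hdc, Prss34 and Mcpt8 rose (3 adjusted over the list alone, median 0.37). The histidine decarboxylase gene Hdc was at 6.12 ± 1.47 in WT and 36.0 ± 16.5 in KLHL3-KI spleen. The basophil proteases Prss34 and Mcpt8 were near the limit of detection in WT, at 0.371 ± 0.209 and 0.164 ± 0.0848, and at 4.65 ± 1.28 and 2.37 ± 1.33 in KLHL3-KI spleen.
The limma camera adjusted p was 1.82e-21 for neutrophil, 1.07e-11 for megakaryocyte, 0.0144 for mast cell and 0.0130 for monocyte genes. These calls were lost at adjusted p = 0.441 with an estimated correlation for the first 3 lists and adjusted p = 0.496 with an estimated correlation for monocytes. After quantile normalization, with equal total reads and without a variance trend 4 monocyte genes rose, and that list did not pass after quantile normalization (0.0701). Without WT replicate 2, 2 monocyte genes rose and that list did not pass (camera adjusted p = 0.132, range over the preset-correlation alternatives 8.21e-04 to 0.132). A robust variance model ended the calls of Ngp, Ltf, Camp and Chil3 (limma adjusted p = 0.0753, 0.0903, 0.107 and 0.0705). Cx3cr1 was not called without WT replicate 1 (0.149) or without a variance trend (0.0659), nor was Mcpt8 without WT replicate 1 or 2 (0.0575 and 0.0893).

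T cell and B cell genes fell. Of 29 T cell genes, 25 fell and none rose (27 fell adjusted over the list alone, median -0.72). Lef1, a transcription factor of naive T cells, fell by 1.16 (SE 0.11), Bcl11b, which keeps T cell identity, fell by 0.94 (SE 0.11), and Cd6 fell by 0.97 (SE 0.12), with limma adjusted p values of 5.60e-05, 2.22e-04 and 4.37e-04. Of 21 B cell genes, 17 fell and none rose (20 fell adjusted over the list alone, median -0.64). Fcer2a fell by 0.89 (SE 0.11) and the immunoglobulin D constant gene Ighd fell by 0.76 (SE 0.11). Of 14 germinal centre B cell genes, 7 fell (11 adjusted over the list alone, median -0.55), with Mef2b going from 4.88 ± 0.579 to 1.25 ± 0.108 and Nuggc from 6.47 ± 0.495 to 2.13 ± 0.258. Of 12 MHC class II and antigen presentation genes, 10 fell (10 adjusted over the list alone, median -0.44), among them the class II transactivator Ciita, which fell by 0.77 (SE 0.12), and H2-Ob, which fell by 0.75 (SE 0.10).
Of 19 dendritic cell genes, 8 fell (9 adjusted over the list alone, median -0.30), including Irf8, which fell by 0.45 (SE 0.09). Cd8a, which fell as well, stands in the T cell list too, so these falls are not particular to dendritic cells. Of 19 NK cell genes, 4 fell (4 adjusted over the list alone, median -0.27), namely Eomes, Txk, Klrk1 and Ncr1, which fell by 0.81, 0.47, 0.39 and 0.55. The plasma cell list did not pass (camera adjusted p = 0.365, median -0.07): of 22 members, Ell2 and the kappa light chain gene Igkc rose and Tnfrsf13b and Irf4 fell (2 and 2 adjusted over the list alone). The 8 largest falls, after 16 gene models and receptor segments were passed over, were in Pde2a, Ccl21a, Dsc2, Mef2b, Nuggc, Fam129c, Lef1 and Fcamr. The phosphodiesterase Pde2a fell by 1.81 (SE 0.18), the lymphoid homing chemokine Ccl21a, which has near-identical copies, fell by 1.45 (SE 0.24), the desmosomal gene Dsc2 fell by 1.45 (SE 0.29), Fam129c fell by 1.21 (SE 0.20) and the immunoglobulin receptor Fcamr fell by 1.11 (SE 0.20).
The limma camera adjusted p was 3.54e-15 for T cell, 7.52e-11 for B cell, 1.41e-05 for germinal centre, 4.11e-06 for MHC class II, 0.00135 for dendritic cell and 0.0239 for NK cell genes. These calls were lost at adjusted p = 0.441 with an estimated correlation for T cell, MHC class II, dendritic and NK cell genes, adjusted p = 0.442 with an estimated correlation for B cell genes and adjusted p = 0.468 with an estimated correlation for germinal centre genes. Without WT replicate 1, 13 T cell, 9 B cell, 4 germinal centre, 3 MHC class II, 1 dendritic cell and 0 NK cell genes fell. With WT replicate 2 left out, 5 B cell, 4 germinal centre, 3 MHC class II, 4 dendritic cell and 0 NK cell genes fell. Irf8, Dsc2, Fcamr, Igkc, Irf4, Ell2 and Tnfrsf13b lost their calls there (limma adjusted p from 0.0630 to 0.118), and Dsc2, Igkc and Irf4 also without WT replicate 1 (0.0574, 0.114 and 0.0806). Without KLHL3-KI replicate 2, 5 MHC class II, 4 dendritic cell and 2 NK cell genes fell, the NK cell list did not pass (0.0777) and neither did Igkc (0.154). The NK cell list also missed the threshold after quantile normalization (0.0701), with haemoglobin, immunoglobulin and mitochondrial genes removed (0.0535) and with equal total reads (0.0631). The call of Igkc was lost after quantile normalization (0.164) and with equal total reads (0.0621), and that of Ccl21a with a robust variance model (0.173). Of the plasma cell genes 1 rose and 7 fell after quantile normalization and with equal total reads, and 7 NK cell genes fell there. For plasma cell genes 5 rose and 5 fell without KLHL3-KI replicate 1, 1 and 4 without KLHL3-KI replicate 2, 1 and 2 without WT replicate 1, and 0 and 1 without WT replicate 2. In a fit with no variance trend 16 T cell, 7 B cell, 2 MHC class II, 3 dendritic cell, 2 NK cell and 0 plasma cell genes fell. With haemoglobin, immunoglobulin and mitochondrial genes removed and with equal total reads 11 germinal centre genes fell. Calls were lost without a variance trend for Irf8, Tnfrsf13b, Ell2, Irf4, Igkc, Txk and Klrk1 (0.0510 to 0.0889), with DESeq2 for Txk, Klrk1 and Ncr1 (0.0914 to 0.249), and with no filter for Igkc and Ncr1 (0.0727 and 0.0753). Klrk1 and Ncr1 were also not called without KLHL3-KI replicate 1 (0.0769 and 0.110).

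**Figure D3:**
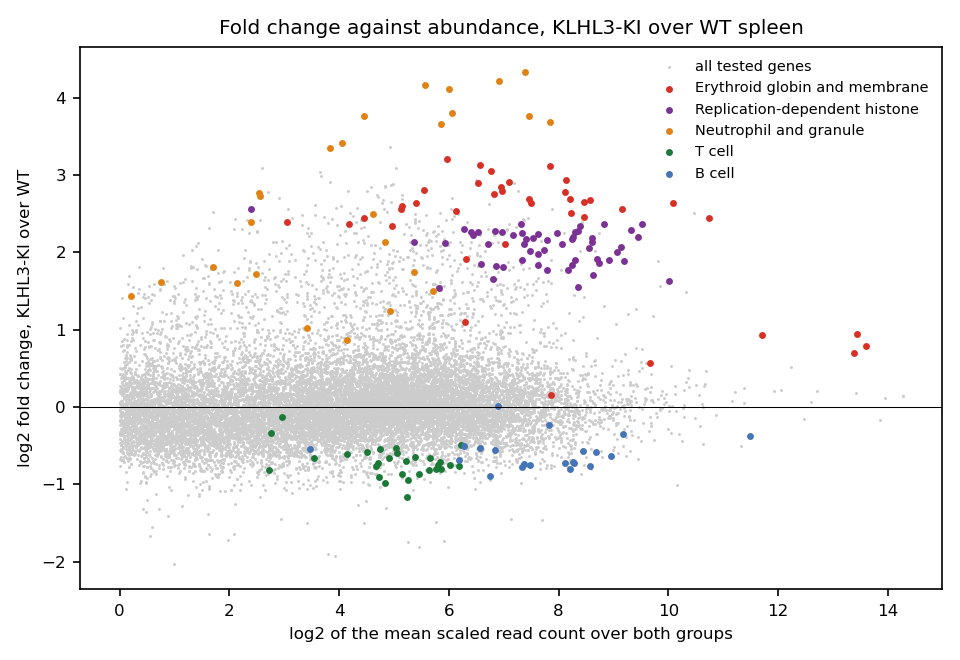
Log2 fold change, KLHL3-KI over WT, against the log2 mean scaled read count of all 16970 tested genes (grey), with the erythroid, histone, neutrophil, T cell and B cell lists in colour. The 4 adult globin genes lie at high abundance with fold changes from 0.69 to 0.95, under most other erythroid genes.

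Genes of the oxidative stress response and immediate early and heat shock genes rose in part. Of 24 NRF2 oxidative stress genes, 16 rose and none fell (17 adjusted over the list alone, median 0.52). Peroxiredoxin 2 (Prdx2), an abundant red cell antioxidant, rose by 2.02 (SE 0.12), and the glutathione synthesis genes Gclm and Gclc rose by 1.59 (SE 0.12) and 1.48 (SE 0.11). Of 32 immediate early and heat shock genes, 14 rose and 2 fell (17 and 2 adjusted over the list alone, median 0.47). The transcription factor Fos went from 3.09 ± 0.849 to 18.4 ± 3.93, the phosphatase Dusp1 rose by 1.80 (SE 0.12) and the chaperone Hspb1 by 1.36 (SE 0.13), while Klf2 and Egr3, named after their values were seen, fell by 0.70 and 0.65. Of 13 mitochondrially encoded genes, mt-Nd6 rose by 0.48 (SE 0.11) and none fell (1 adjusted over the list alone, median 0.25, mean 0.49). The highest log2 fold change in that list was 2.56, in a gene that did not pass. Only 12 members held reads once KLHL3-KI replicate 1 was left out. Of 31 CUL3 adaptor and ubiquitin-proteasome genes, 11 rose and 2 fell (13 and 5 adjusted over the list alone, median 0.13). The adaptor Klhl12 rose by 1.23 (SE 0.10) and the ubiquitin ligase Rnf123 by 1.06 (SE 0.09), and Rhobtb2 and Klhl42, named after their values were seen, were those that fell. The asparagine synthetase gene Asns rose by 2.49 (SE 0.21) and the stress transcription factor Atf4 by 0.69 (SE 0.11) within the unfolded protein response list. Of its 21 members 4 rose (3 adjusted over the list alone), the others being Canx and Ddit3. In the inflammatory list, Il1b rose by 1.74 (SE 0.13) and Socs3 by 0.84 (SE 0.13). Of its 14 members 4 rose and 1, Tnf, fell (5 and 2 adjusted over the list alone), the other rises being Cxcl1 and, named after its values were seen, Ccl2.
The limma camera adjusted p was 9.38e-08 for NRF2, 8.08e-04 for immediate early and 0.0261 for mitochondrial genes. These calls were lost at adjusted p = 0.441 with an estimated correlation for NRF2 and immediate early genes and adjusted p = 0.468 with an estimated correlation for mitochondrial genes. The CUL3 adaptor (0.0726), unfolded protein response (0.0816) and inflammatory (0.151) lists did not pass. With WT replicate 2 left out, 7 NRF2, 8 immediate early, 6 CUL3 adaptor and 2 unfolded protein response genes rose. Without WT replicate 1, 10 NRF2, 6 CUL3 adaptor and 2 inflammatory genes rose and the unfolded protein response list passed (0.00747). Without KLHL3-KI replicate 2, 10 NRF2 and 7 CUL3 adaptor genes rose. The calls of mt-Nd6, Canx, Ddit3, Tnf, Egr3, Rhobtb2, Klhl42 and Ccl2 were lost without WT replicate 2 (limma adjusted p from 0.0687 to 0.259), and those of Tnf, Cxcl1, Ddit3, Klhl42 and Ccl2 without WT replicate 1 (0.0506 to 0.201). Ddit3, Klhl42 and Ccl2 also lost theirs without KLHL3-KI replicate 1 (0.108, 0.108 and 0.0778). Ddit3 was not called in several other settings, with a range up to 0.259, among them quantile normalization (0.0805), haemoglobin, immunoglobulin and mitochondrial genes removed (0.0979), equal total reads (0.127), edgeR (0.0547) and DESeq2 (0.231). Without a variance trend mt-Nd6, Canx, Ddit3 and Klhl42 lost their calls (0.0548 to 0.110), as did mt-Nd6 after quantile normalization (0.0575) and Klhl42 with DESeq2 (0.0974). The mitochondrial list did not pass without KLHL3-KI replicate 1 (0.175) or with quantile normalization (0.314), equal total reads (0.0938) or a mean of at least 5 (0.0614). Of its genes 3 rose and 1 fell without KLHL3-KI replicate 2, 2 rose without KLHL3-KI replicate 1, 4 rose with a replicate block, and 0 rose and 1 fell after quantile normalization. With no variance trend 10 NRF2, 6 CUL3 adaptor, 2 unfolded protein response and 0 mitochondrial genes rose. Of the CUL3 adaptor genes 7 rose and 4 fell after quantile normalization and 6 rose and 5 fell with equal total reads.

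The remaining lists held genes that went both ways or few that passed, and none of these lists passed limma camera. Of 17 haematopoietic progenitor genes, 5 rose and 2 fell (5 and 4 adjusted over the list alone). Gfi1b, a repressor active in erythroid and megakaryocytic cells, rose by 2.65 (SE 0.15), Myb by 1.39 (SE 0.18) and Muc13 by 1.62 (SE 0.21), while Adgrg1 also rose and Flt3 and Slamf1 fell. The stem cell markers Kit and Cd34 did not pass, at 46.9 and 26.9 in WT and 52.4 and 25.9 in KLHL3-KI spleen. Adgrg1, Flt3, Slamf1, Kit and Cd34 were named after their values were seen, as were Ifih1, Stat2, Ifi213, Ddx58 and Cxcl13 below. Its median was -0.05, its mean 0.33 and its test direction up (adjusted p = 0.486). Of 43 interferon response genes, Isg15, Rsad2, Oas3 and Ifih1 rose and Gbp4, Stat2, Ifi213 and Ddx58 fell (4 and 4 adjusted over the list alone). Isg15 was at 12.7 ± 4.86 in WT and 39.9 ± 7.65 in KLHL3-KI spleen. In the circadian clock list the repressor Nr1d1 fell by 0.91 (SE 0.18) and Per2 rose by 0.87 (SE 0.23). The rise of Per2 ran from 0.51 to 1.22 without 1 library. Of the 20 members of the clock list 3 rose and 4 fell (3 and 4 adjusted over the list alone). In the stroma and endothelium list Ccl21a, Ccl19, Madcam1 and Cxcl13 fell and the smooth muscle gene Tagln rose by 0.56 (SE 0.10), out of 30 members (3 fell and 1 rose adjusted over the list alone). Of 23 hypoxia and glycolysis genes, 3 rose and 3 fell (4 and 3 adjusted over the list alone), with hexokinase Hk1, known for its red cell isoform, at 1.29 (SE 0.13). Of 16 adipose genes, Plin4 and Lipe fell (0 adjusted over the list alone). Of 3 tested pancreatic acinar genes Cela1 went from 6.77 ± 0.707 to 14.9 ± 1.77 while Reg2 and Gp2 did not pass. Among the Y-linked genes, Kdm5d fell by 0.40 (SE 0.10) and Ddx3y, Eif2s3y and Uty did not pass.
The camera adjusted p was 0.365 for interferon, 0.256 for clock, 0.0816 for stroma, 0.955 for hypoxia and 0.620 for adipose genes, the last with a median of 0.06, a mean of -0.02 and test direction down. Without WT replicate 1, 7 interferon genes rose and 0 fell, and that list turned up (median 0.17, adjusted p = 0.0647). Without WT replicate 2 the interferon list passed as down (1.22e-04). Of its genes 3 rose and 7 fell after quantile normalization, and 3 rose and 10 fell with haemoglobin, immunoglobulin and mitochondrial genes removed and with equal total reads. Under these 3 scalings 10 stroma, 5 progenitor and 3 adipose genes fell. With no variance trend 0 interferon, 0 progenitor, 0 adipose, 2 stroma, 2 clock and 1 hypoxia genes fell. The stroma list passed without WT replicate 1 (0.0236) and without KLHL3-KI replicate 1 (0.00193), where 9 of its genes fell, and 2 of them fell without each of the other 3 libraries. Stroma genes that rose were 3 without WT replicate 2 and 4 without KLHL3-KI replicate 2. Progenitor genes that fell were 0 without WT replicate 1, 1 without WT replicate 2 or KLHL3-KI replicate 2, and 4 without KLHL3-KI replicate 1. Hypoxia genes that fell were 1 without WT replicate 1 or 2. The adipose list turned up without KLHL3-KI replicate 1 (0.430), with 3 rises and 1 fall, and passed as down without KLHL3-KI replicate 2 (0.0454). Of the clock genes 0 rose and 1 fell without WT replicate 1 and 1 rose and 1 fell without WT replicate 2, and 1 rose and 2 fell without KLHL3-KI replicate 2. Nr1d1 lost its call without WT replicate 2 (0.0863) and Per2 without WT replicate 1 (0.148). Kdm5d, Plin4 and Lipe lost their calls without WT replicate 1 (0.126, 0.199 and 0.125), WT replicate 2 (0.101, 0.0829 and 0.239) or KLHL3-KI replicate 2 (0.0991, 0.119 and 0.0702). Gbp4, Stat2, Ifi213, Ddx58, Adgrg1, Flt3, Slamf1, Ccl19 and Cxcl13 lost theirs without WT replicate 1 (0.0724 to 0.289), and Ifih1, Madcam1, Cxcl13, Slamf1 and Ddx58 theirs without WT replicate 2 (0.0608 to 0.183). Madcam1, Cxcl13, Slamf1 and Ddx58 also lost theirs without KLHL3-KI replicate 2 (0.0635, 0.186, 0.263 and 0.107). Ifih1 was also not called after quantile normalization (0.0913), with haemoglobin, immunoglobulin and mitochondrial genes removed (0.0508) and with equal total reads (0.0798), nor were Oas3 and Cxcl13 with a robust variance model (0.0552 and 0.0505). Calls were lost without a variance trend for Ifih1, Gbp4, Stat2, Ifi213, Ddx58, Per2, Madcam1, Cxcl13, Plin4, Lipe, Kdm5d, Adgrg1, Flt3 and Slamf1 (0.0511 to 0.146). With DESeq2 they were lost for Madcam1, Plin4, Lipe, Flt3 and Slamf1 (0.0533 to 0.210), and with no filter for Plin4, Lipe, Slamf1 and Cxcl13 (0.0593 to 0.0692). Lipe was also not called without KLHL3-KI replicate 1 (0.130), and Slamf1 with edgeR (0.0530).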

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

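All alternatives were chosen before the data were examined except equal total reads and camera without a variance trend, which were chosen after seeing the data. None of the 166 named genes and 24 lists that passed changed direction under any alternative run. For genes this was fixed in advance in many of them. The groups did not overlap for any of the 3866 genes that passed, so leaving out 1 library or changing the pseudocount could not turn their sign. The filter, the variance settings and the replicate block leave the fold change as it is. Changed scalings, edgeR and DESeq2 could have turned a sign and did not. Of the 166 named genes 78 lost the call under at least 1 alternative (279 of 2808 comparisons). All 24 lists lost it with an estimated correlation, where the count of changed lists was 0 of 30 (0 also at an unadjusted p of 0.05) against 19. The NK cell list did so at an estimated correlation of -0.00938, so these losses do not measure correlation alone. Without 1 library, the count of genes that passed (3866) ran from 1653 to 4580, of those that rose (2583) from 1386 to 2921 and of those that fell (1283) from 267 to 1659. The count that fell was 2369 after quantile normalization, 2971 with haemoglobin, immunoglobulin and mitochondrial genes removed and 3126 with equal total reads. These scalings shifted the median of all genes from -0.01 to -0.10, -0.14 and -0.16. Equal total reads took out the library factors (1.05 and 1.07 in WT, 0.947 and 0.939 in KLHL3-KI), which moves all genes down in KLHL3-KI. The removal setting also made the remaining totals equal, so its shift cannot be put down to the removed genes. The cause of the shift with quantile normalization was not tested. Without a variance trend 2462 passed and 659 fell, and with DESeq2, which gave no adjusted p for 1645 genes, 793 fell; the cause was not tested. At an adjusted p of 0.1, a wider threshold by construction, 1991 fell. Of the 3866 genes, 3786 passed in edgeR in the same direction and 2791 in DESeq2. With a replicate block (paired numbers) 4130 passed, 2715 up and 1415 down.

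Some lists near the threshold changed call with no filter on low values, where mast cell genes did not pass (0.0584) and CUL3 adaptor (0.0216), unfolded protein response (0.0453) and inflammatory genes (0.0356) did; the monocyte list did not pass after quantile normalization (0.0701).

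Reversals were limited to results that did not pass, which for genes was in part fixed in advance, and the cause was not tested. On the log2 scale, quantile normalization gave Klhl2 -0.10, Cul3 -0.027, Rbx1 -0.10, Nedd8 -0.017, Stk39 -0.085, Oxsr1 -0.0061, Cab39l -0.16 and Kit -0.011, and medians of -0.11 for the hypoxia, -0.15 for the stress erythropoiesis and -0.12 for the ribosomal list. Removing haemoglobin, immunoglobulin and mitochondrial genes gave Klhl2 -0.082, Cul3 -0.031, Rbx1 -0.080, Stk39 -0.11, Cab39l -0.13, Siglecf -0.036, hypoxia -0.12 and ribosomal -0.074. Equal total reads gave Klhl2 -0.11, Cul3 -0.060, Rbx1 -0.11, Nedd8 -0.011, Stk39 -0.13, Oxsr1 -0.012, Cab39l -0.16, Kit -0.013, Ccr3 -0.020, Siglecf -0.054, hypoxia -0.15, stress erythropoiesis -0.17 and ribosomal -0.10. Rpph1 was 0 after quantile normalization, and Cab39l was -0.0099 with edgeR and -0.0021 with DESeq2. The test direction turned for the WNK-KLHL3 list with no filter (median 0.015), a mean of at least 5 (0.054), no variance trend (0.025) and camera without a variance trend (0.025). With a mean of at least 5 it also turned for hypoxia (0.018) and stress erythropoiesis (-0.024). Without 1 library the values ran from -0.077 to 0.059 for Cab39, -0.073 to 0.050 for Slc12a2, -0.25 to 0.18 for Gp2, -0.16 to 0.059 for Uty, -0.17 to 0.081 for Ddx3y, -0.18 to 0.030 for Eif2s3y and -0.16 to 0.056 for Cd34. They ran from -0.024 to 0.14 for Rbx1, -0.048 to 0.099 for Stk39, -0.066 to 0.076 for Cab39l, -0.89 to 0.22 for Slc12a1, -0.63 to 0.079 for Slc12a3 and -0.012 to 0.12 for Klhl2. For Ccr3 they were -0.096 to 0.39, for Siglecf -0.36 to 0.46 and for Rmrp -0.27 to 0.16. List medians ran from -0.30 to 0.17 for interferon, -0.32 to 0.37 for adipose, -0.015 to 0.059 for stress erythropoiesis, 0.0090 to 0.076 for WNK-KLHL3, 0.0013 to 0.079 for hypoxia, 0.0056 to 0.13 for ribosomal genes and -0.46 to 0.16 for RNA without a poly(A) tail.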

Other observations

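The lists and tests in this part were chosen only after the results were seen, except that the prediction for RNA without a poly(A) tail was written before its values were seen. Genes of eosinophil granules were higher in KLHL3-KI spleen, where 5 of 9 members rose and none fell (5 adjusted over the list alone, median 0.59). Major basic protein (Prg2) rose by 2.43 on the log2 scale (SE 0.20) to 71.1, eosinophil peroxidase (Epx) by 2.98 (SE 0.42) and the ribonuclease Ear6 by 2.78 (SE 0.26), and Ear1 and Ear2 rose too. The surface receptors Ccr3, Siglecf and Il5ra did not pass, and the list's limma camera adjusted p of 0.00279 became adjusted p = 0.439 with an estimated correlation. The call of Epx was lost with a robust variance model (limma adjusted p = 0.113) and that of Ear2 without WT replicate 1, WT replicate 2 or KLHL3-KI replicate 2 (0.104, 0.130 and 0.135). Chemokines and receptors that organise the white pulp were lower, with 10 of 12 falling (12 adjusted over the list alone, median -0.66). Among them were Ccl21a, Ccl19, Cxcl13, Ccr7, lymphotoxin beta (Ltb), which fell by 0.72 (SE 0.14), and Grem1, which fell by 1.07 (SE 0.27). The log2 fold change of Grem1 ran from -1.50 to -0.65 without 1 library. The list's limma camera adjusted p was 1.06e-06, and adjusted p = 0.439 with an estimated correlation. Without WT replicate 2 the calls of Ltb, Grem1 and Cxcl13 were lost (limma adjusted p = 0.0872, 0.151 and 0.0813), and without WT replicate 1 also those of Ccl19 and Ccr7 (0.0724 and 0.0690). Of 10 naive T cell genes 6 fell (8 adjusted over the list alone, median -0.49), and of 14 regulatory and effector T cell genes Ikzf2, Il2ra, Cxcr3 and Icos fell (5 adjusted over the list alone, median -0.34), all 4 of which lost the call without WT replicate 1 (limma adjusted p from 0.0865 to 0.240). Il2ra, Cxcr3 and Icos also lost theirs without WT replicate 2 (0.0684, 0.144 and 0.0526) and with DESeq2 (0.0887, 0.185 and 0.0653). Without a variance trend Ear2, Ltb, Grem1, Cxcl13, Ikzf2, Il2ra, Cxcr3 and Icos lost their calls (0.0531 to 0.146). Their limma camera adjusted p values were 3.24e-05 and 0.00325, with adjusted p = 0.398 with an estimated correlation and adjusted p = 0.439 with an estimated correlation.

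Among signals between red cell precursors and their surroundings, the transferrin receptor 2 gene Tfr2 rose by 2.60 (SE 0.21), stem cell factor (Kitl) by 0.62 (SE 0.12) and erythroferrone (Erfe) by 0.99 (SE 0.31). Id3 and Smad7, targets of BMP signalling, fell by 0.60 and 0.44, while Bmp4 did not pass at 4.57 in WT and 5.67 in KLHL3-KI spleen. Without WT replicate 2, Kitl, Erfe, Id3 and Smad7 lost their calls (limma adjusted p = 0.0904, 0.126, 0.145 and 0.254), and the last 3 also without WT replicate 1 (0.256, 0.101 and 0.135). Without a variance trend all 4 lost theirs (0.0570 to 0.119), and Erfe also did without KLHL3-KI replicate 2 (log2 fold change 0.49, adjusted p 0.258), after quantile normalization (0.0576), with equal total reads (0.0705) and with a robust variance model (0.0742). The list of 15 genes did not pass (3 rose and 2 fell, also adjusted over the list alone, camera adjusted p = 0.977), with a median of -0.02, a mean of 0.22 and test direction up. Of 20 cholesterol synthesis genes 2 fell (1 adjusted over the list alone), among them Srebf2, which lost the call without WT replicate 2 (limma adjusted p = 0.0592). That list had a camera adjusted p of 0.0630 and passed without WT replicate 2 (0.00446) or KLHL3-KI replicate 1 (0.0335), with a mean of at least 5 (0.0445), with haemoglobin, immunoglobulin and mitochondrial genes removed (0.0489) and with equal total reads (0.0461), in a range from 0.00446 to 0.362. Of 77 cytosolic ribosomal protein genes Rps2, Rpl41, Rpl27, Rpl29 and Rpl7a rose and none fell (0 adjusted over the list alone, camera adjusted p = 0.148), and all 5 lost the call without WT replicate 2 (limma adjusted p from 0.0934 to 0.256). The median of that list was 0.06 and turned to -0.12 after quantile normalization, -0.074 with haemoglobin, immunoglobulin and mitochondrial genes removed and -0.10 with equal total reads, and the list passed without WT replicate 1 (0.00358). The mature neutrophil list passed (6 of 6 rose, 6 adjusted over the list alone, camera adjusted p = 1.16e-06, and adjusted p = 0.439 with an estimated correlation). All 4 primary granule and all 4 adult globin genes rose, and 0 of the 13 tested RNAs without a poly(A) tail passed (camera adjusted p = 0.277), while that list passed as down without KLHL3-KI replicate 1 (0.00291).

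Erythroid and granule genes were higher in KLHL3-KI spleen, and more blood left in these spleens was weighed as the technical explanation. Blood brings globin transcripts in a larger ratio to precursor genes than the spleen holds. Yet the median log2 fold change of the adult globin genes (0.86, 4 genes) lay below that of the other 35 erythroid genes (2.64). The difference was -1.778 (exact permutation test over genes, p = 0.0103). That p covers genes and not samples, the globin copies share reads, and the contrast was chosen after the values were seen. Circulating neutrophils would raise the genes of mature neutrophils most, yet the primary granule genes Mpo, Elane, Prtn3 and Ctsg (median 3.50) lay above the 6 mature genes (median 1.73) by 1.766 (exact permutation test over genes, p = 0.0286). That contrast rests on which late genes are taken, since with S100a8 and S100a9 among the mature genes the difference was 1.56 (exact permutation test over genes, p = 0.109). Against all 22 other genes of the neutrophil list it was 1.233 (exact permutation test over genes, p = 0.254). Those genes include further granule genes such as Ngp, Ltf and Camp, so that difference does not set mature against precursor genes. The globin value argues against residual blood as the whole source of the erythroid rise. For the neutrophil genes residual blood stays open, since these sets do not decide it. A larger number of red cell precursors in KLHL3-KI spleen is a candidate explanation, and a larger number of granulocyte precursors stays open beside blood. A link to the genotype was not tested, since genotype goes with anything else that differed between these 2 pairs of samples.

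Histone genes were higher in KLHL3-KI spleen, and their transcripts lack a poly(A) tail, so that a difference in how such RNA was recovered could raise them. Under that explanation the other RNAs of this kind would rise by a median of at least 1 on the log2 scale. The upper quartile of 13 small nuclear, nucleolar and related RNAs was -0.02514 and their median -0.20, and the median ran from -0.46 without KLHL3-KI replicate 1 to 0.16 without KLHL3-KI replicate 2, so the sign of this small value rests on single libraries. The abundant Rpph1 was at 3603 in WT and 4175 in KLHL3-KI spleen. This argues against a difference in recovery shared by all such RNA as the whole cause. The comparison RNAs, 13 tested of 21 listed, are small RNAs, so a difference in recovery of histone transcripts alone was not tested. A larger share of dividing cells may underlie the histone rise, since all 36 cell cycle genes rose too, and that was not tested apart from the genotype.

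T cell and B cell genes were lower in KLHL3-KI spleen, and equal dilution of all resident cells by added erythroid and myeloid cells could lower them. Equal dilution predicts the same fall for NK cell and stroma genes, yet the median of the 29 T cell genes (-0.72) lay below that of the 49 NK cell and stroma genes (-0.15) by a difference of -0.5703 (permutation test over genes, p = 2e-05, the smallest that 100000 resamples can give). The median of the 21 B cell genes (-0.64) lay below it by a difference of -0.4835 (permutation test over genes, p = 2e-05, the same limit). Genes of 1 list are not independent of each other. The contrast was chosen after these medians were seen, so its p is not an independent test. The NK cell list, which passed as down, had a median of -0.27 and the stroma list one of -0.12. The share of all reads in T cell genes went from 0.143% in WT to 0.0754% in KLHL3-KI libraries. That of B cell genes went from 0.9458% to 0.5922%, of NK cell genes from 0.02746% to 0.02017% and of stroma genes from 0.2496% to 0.1923%. Only 13 of the 19 NK cell genes had a mean of at least 5, and the pseudocount makes falls of low genes smaller. For T cell genes the medians argue against equal dilution as the whole cause, and part of the fall may still be dilution. For B cell genes the fall in shares lay nearer to those of NK cell and stroma genes than the medians did. That gap in shares was not tested, so equal dilution is not decided for B cell genes. A lower number of T and B cells relative to NK cells and stroma, or a genotype effect within lymphocytes, stay open and untested.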
